A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

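Roots of rice (Oryza sativa Japonica, Nipponbare) from control nutrients, N deficiency and P deficiency were sequenced as TruSeq RNA libraries, with 3 biological replicates in each of 3 groups, per the labels. The deposited data were 2 tables, of 35128 genes for N deficiency against control and 35059 for P deficiency against control, both holding the same control libraries. HISAT2 2.0.5 and the human assembly name hg38 are listed in the submitters' processing notes. The genome build behind the rice coordinates, the read counter, its strand setting, the annotation and the size-factor method are not given in the sources used here.

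Each library column held a normalised signal, which the authors made by dividing gene read counts by 1 size factor per library, separately in each deposited table. Whole reads were recovered from these values for 100% of values in the 12 library columns within a tolerance of 0.001, and 0 control reads differed between the tables over 34285 shared genes. Group mean columns, the log2 fold change and the p-value and adjusted p-value columns were the authors' own, per the file headers, with a test that is not given in the sources used here. Genes in each table had at least 2 reads over its 6 libraries. Symbols came from the deposited tables for 208 genes and protein domains for 20458. Of 105 hand-listed locus IDs, 2 were left out because their deposited domain named another protein and 5 were not in the tables used here. Of the hand-listed symbols, 70 were found in a RefSeq gene table of assembly ASM3414082v1, 68 of them near the locus on the same chromosome. Neither IRO2 nor TOM1 was, and the locus used as IRO2 carries a domain of unknown function in the deposited tables.

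Tests used limma 3.58.1 (R 4.3.3), with an intensity trend, on log2(value + 1). Genes with a mean value of at least 1 in 1 of the groups were tested, and an adjusted p under 0.05 (Benjamini-Hochberg) was the threshold. N and P deficiency were each tested against control on the 6 libraries of their own deposited table, which were scaled separately. N against P deficiency was a contrast over all 9 libraries, on recovered reads rescaled with median-of-ratios size factors. The design fixed before the data were examined named edgeR for counts and limma for normalised values, and limma was used because the deposited values were normalised. The contrast of N against P deficiency was first fitted with edgeR, which called 1330 genes, and was changed to limma after that count was seen so that each comparison used the same test. Fold changes on the log2(value + 1) scale understate the change of low genes.

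The 29 gene lists were P starvation regulators, phosphate transporters, nitrate and ammonium transporters, nitrogen assimilation, nitrate-response regulators, iron uptake and storage, strigolactone, diterpenoid phytoalexin synthesis, purple acid phosphatases, glycerophosphodiester phosphodiesterases, sulfolipid and galactolipid synthesis, SPX domain proteins, the NRT1/PTR family, amino acid transporters, glutaredoxins, peroxidases, WRKY factors, ethylene response factors, response regulators, ribosomal proteins, histones, aquaporins, expansins, xyloglucan and cellulose enzymes, Casparian strip proteins, heat shock proteins, glutathione transferases, lipoxygenase and jasmonate, and photosynthesis genes as markers of shoot tissue. Pattern lists were matched on the deposited domain descriptions, and sulfolipid and galactolipid synthesis, aquaporins and expansins matched 0 genes under their patterns. The 25 lists with at least 5 members were tested in 3 comparisons with camera (limma), a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 75 tests. Of 31 list calls, 4 held with an estimated correlation: SPX domain genes under P deficiency, and SPX domain genes, phosphate transporters and glycerophosphodiester phosphodiesterases in N against P deficiency. Domain enrichment, chosen after the data were seen, used a hypergeometric test, one-sided, over 4176 tests with Benjamini-Hochberg adjustment, with tested genes that carry a domain as background.

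Named genes followed a fixed rule. It took the 6 largest rises and falls per comparison among passing genes with at least 5 CPM in the higher group, non-overlapping groups and an informative description. It added up to 4 passing members per list by size of change, well-known members whatever their test, and the 5 largest shared rises, shared falls and opposite changes. Non-overlap of 3 against 3 libraries has a 10% share by chance. Genes outside the rule are described as named after their values were seen.

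Alternatives were edgeR 4.0.16 on the recovered reads with TMM or DESeq2 size factors and several filters, DESeq2 1.42.0, a pseudocount of 0.1, no filter, a fold limit, the replicate number as a block, 1 fit over 9 libraries and each library left out in turn. The same steps tested on simulated reads with 100 genes changed 2-fold and 100 changed 4-fold recovered 54% and 88% of them for N deficiency (32286 genes, 8 false calls), 44% and 88% for P deficiency (32315 genes, 13 false calls) and 53% and 97% for N against P deficiency (32773 genes, 9 false calls). The changed genes were drawn only from well-covered genes, so these shares do not hold for genes of low level. A library that stands apart, such as P library 3, was not simulated. A fold against a group without reads was set against a floor of 3 reads over the group. Ratios with 1 to 3 reads carry an exact 95% interval. Intervals cover counting error only, and floors only that of the group without reads. Genes with near-identical copies (NRT2.1 and NRT2.2, PT9 and PT10, NAS1 and NAS2) and overlapping or antisense genes are uncertain, since the counting of shared reads is not given in the sources used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table (1.17.8) were used, with random seed 20240101.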

Results

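Messenger RNA was profiled by RNA sequencing in roots of rice (Oryza sativa, the Japonica cultivar Nipponbare, whose genome is the usual rice reference) grown with control nutrients, without enough nitrogen (N deficiency) or without enough phosphorus (P deficiency). Each of the 3 groups had 3 libraries, and the same 3 control libraries served both deficiencies. Reads assigned to genes ranged from 17931136 to 22752604 per library. In M reads, the means were 20.5 ± 2.43 in control, 21.4 ± 0.815 under N deficiency and 20.3 ± 1.58 under P deficiency (SD, n = 3). Levels below are mean normalised reads ± SD with n = 3 per group. Log2 fold changes carry their SE and are on the log2(value + 1) scale, which understates the change of low genes. Control means differ slightly between the N and P comparisons because the authors scaled their 2 tables separately. Coordinates are those of the deposited tables, whose genome build is not given in the sources used here.

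Groups separated along the leading principal components, which held 36.6% and 24.5% of the variance. P library 3 lay apart from the other libraries on the third component, at -73.6 against -18.1 to 31.3 in the other 8 libraries. Replicate pairs differed beyond counting noise in every group, with a chi-square per degree of freedom from 8.75 between control libraries 1 and 2 to 53.2 between P libraries 2 and 3.

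**Figure D1:**
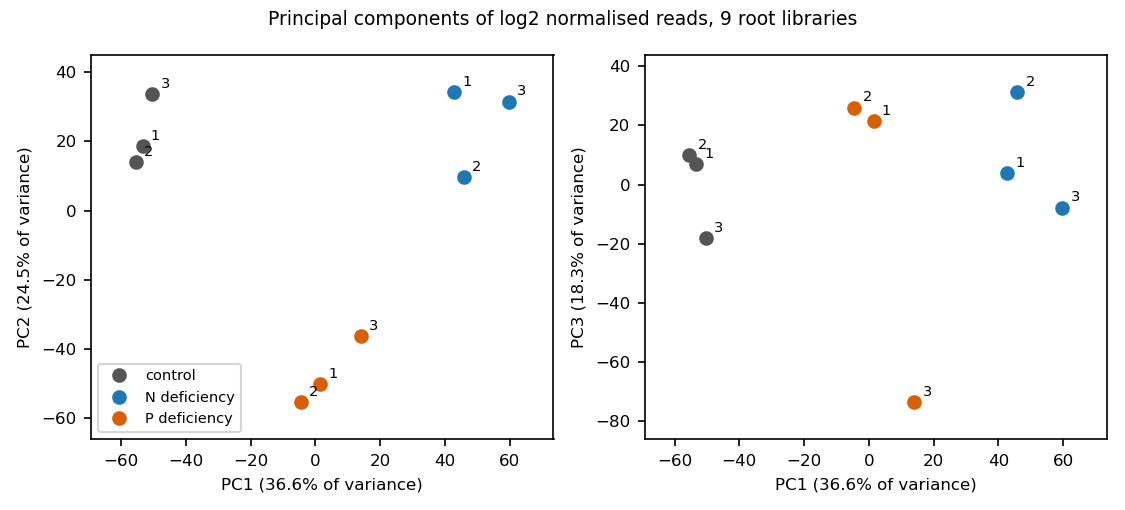
Principal component scores of the 9 root libraries from log2 normalised reads, with the share of variance on each axis label and colour marking the group. The 3 groups separate on components 1 and 2, and P library 3 sits at -73.6 on component 3.

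The comparison of N deficiency with control asks which root genes respond to a shortage of nitrogen. Among high-affinity nitrate uptake genes, NRT2.4 and NAR2.1 rose. NRT2.4, a root nitrate transporter, went from 21.8 ± 7.69 to 8032 ± 900.3 normalised reads, a log2 fold change of 8.50 ± 0.213 (limma, Benjamini-Hochberg adjusted p = 1.1e-06). NAR2.1, the partner protein that NRT2 transporters need, went from 2265 ± 298 to 28315 ± 5607, while NAS1 and NAS2, which make the nicotianamine used for iron uptake and transport, dropped to a few reads. In all, 4194 of 32680 tested genes passed, 2254 higher and 1940 lower under N deficiency, and 2213 of them changed by at least 1 on the log2 scale.

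Of the 16 nitrate and ammonium transporter genes measured, 10 rose, 2 fell and 4 did not pass, with 12 passing when adjusted over the list alone. The list moved up as a set (camera, Benjamini-Hochberg adjusted p = 4.0e-06; adjusted p = 0.26 with an estimated correlation). Set tests with the preset correlation also passed in other splits of the 9 libraries, 6 to 30 per split over the 3 comparisons against 32 in the real split on the same scale. NRT2.1 (chromosome 2, 655324 to 657243) went from 12.6 ± 2.07 to 1240.4 ± 191 normalised reads, log2 fold change 6.51 ± 0.180 (limma, Benjamini-Hochberg adjusted p = 1.7e-06). NRT2.3 (chromosome 1, 29188850 to 29190936) went from 387 ± 55.96 to 11895 ± 3407, log2 fold change 4.91 ± 0.206 (limma, Benjamini-Hochberg adjusted p = 1.5e-05). NRT2.1 and its near-identical neighbour NRT2.2 may share reads, so the split between them is uncertain. NRT2.4 lies on chromosome 1, 20385993 to 20388511, and NAR2.1 on chromosome 2, 23121133 to 23123149 rose by 3.63 ± 0.172 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 2.2e-05). The ammonium transporters AMT1;1 and AMT1;3 rose by 1.15 ± 0.192 and 3.81 ± 0.520 on the log2 scale, whereas AMT1;2 stood at 174 ± 66.7 in control and 155 ± 21.1 under N deficiency and did not pass (limma, Benjamini-Hochberg adjusted p = 0.85). The falls were NRT1.1B, a nitrate transporter and sensor, which went from 5039 ± 982 to 509 ± 1.29, a log2 fold change of -3.28 ± 0.144, and AMT2;3. Both were chosen for naming after their values were seen. A pattern meant for the NRT1/PTR family matched 2 NAR2-type genes instead, and both rose: NAR2.1 and Os04g0480200, the latter by 4.13 ± 0.233 on the log2 scale.

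Nitrogen assimilation genes went both ways, with 4 of 16 higher, 4 lower and 9 passing when adjusted over the list alone, and the set test did not pass (camera, Benjamini-Hochberg adjusted p = 0.67). GS1;1, a cytosolic glutamine synthetase, rose from 10557 ± 342 to 32001 ± 3157 normalised reads, NADH-GOGAT2, a glutamate synthase, from 26.1 ± 2.44 to 105 ± 29.1, and ASN2, an asparagine synthetase, from 750.5 ± 121 to 1649.7 ± 39.9997. The nitrate reductase gene NIA2 fell from 8379 ± 4261 to 2385 ± 487 and ASN1 fell from 10836 ± 537 to 4991 ± 1256. Their log2 fold changes were 1.60 ± 0.131, 1.94 ± 0.245, 1.15 ± 0.127, -1.72 ± 0.309 and -1.15 ± 0.170, with limma, Benjamini-Hochberg adjusted p from 2.6e-04 to 0.008. Fd-GOGAT (0.72) and GDH2 (-0.81), named after their values were seen, passed too, as did NIA1 (-0.98 ± 0.253), whose call was lost without control library 2 or N library 1, 2 or 3 (adjusted p up to 0.11). GS1;2 had a log2 fold change of 0.11 ± 0.155 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.71). Among 6 nitrate-response regulators, 2 rose and 3 fell, and all 6 passed when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.27). The RWP-RK factor NLP1 rose from 1351 ± 71.4 to 3400.2 ± 353, while NIGT1, a GARP-type repressor of nitrate uptake genes, fell from 138 ± 20.004 to 31.9 ± 6.15 and the LOB-domain factors LBD37 and LBD38 fell by 2.02 and 1.91 on the log2 scale. NLP4, named after its values were seen, was the other riser, at 1.13 ± 0.137.

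Iron uptake genes fell as a set, 9 of 14 lower and 1 higher. The count was 11 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.9e-06; adjusted p = 0.072 with an estimated correlation). NAS1 (chromosome 3, 10929507 to 10930895) went from 823 ± 380.5 to 1.02 ± 1.76 normalised reads. A total of 3 reads over the 3 N libraries gave a control to N deficiency ratio of 809.6 with a 95% counting interval of 277 to 3934. NAS2, its tandem neighbour, went from 899 ± 453 to 4.53 ± 2.67, and the iron(III)-phytosiderophore transporter YSL15 from 166 ± 58.9 to 1.30 ± 0.523. The locus known as IRO2, a regulator of iron uptake, went from 386 ± 32.4 to 15.2 ± 7.45, a log2 fold change of -4.67 ± 0.297 (limma, Benjamini-Hochberg adjusted p = 8.3e-05). The deposited tables give this locus a domain of unknown function, and Os01g0952900 lies within its span, so its reads may not all be those of IRO2. The single riser was NAS3, named after its values were seen, at 1.19 ± 0.122. NAS1 and NAS2 are close copies, and reads shared between them could not be told apart here.

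Strigolactone genes included 3 risers and 2 fallers of 8. The count was 7 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.092). The list passed with the rotation test (fry, Benjamini-Hochberg adjusted p = 1.7e-04). The GRAS factors NSP1 and NSP2 rose from 40.4 ± 5.32 to 612 ± 54.2 and from 15.3 ± 2.69 to 81.03 ± 4.78 normalised reads, and D10, a carotenoid cleavage dioxygenase of strigolactone synthesis, rose from 21.3 ± 1.51 to 76.1 ± 7.45. D14, the strigolactone receptor, fell from 28371 ± 4251 to 15071 ± 2152, and D3, named after its values were seen, fell by 0.78 on the log2 scale. Diterpenoid phytoalexin genes moved up as a set, with 2 of 8 higher and 2 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0061; adjusted p = 0.58 with an estimated correlation). The risers were CPS4 and CYP99A3 of the chromosome 4 cluster, at 1.52 ± 0.252 and 1.31 ± 0.198. Amino acid transporters moved up too, 18 of 84 higher and 6 lower. The count was 26 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.9e-04; adjusted p = 0.23 with an estimated correlation). Examples were Os01g0882800 at 2.42 ± 0.219 and Os01g0825800 at -3.73 ± 0.112.

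Photosynthesis genes, fixed as markers of shoot tissue, fell in 31 of 44 cases, none rose. The count was 34 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.9e-19; adjusted p = 0.26 with an estimated correlation). The chlorophyll a-b binding protein gene Os07g0178700 went from 2864 ± 1744 to 57.8 ± 21.2 normalised reads and its neighbour Os07g0178800 from 2567 ± 1443 to 67.2 ± 35.7. Summed reads of the list were 28182, 44855 and 75784 in control libraries 1, 2 and 3, and 10482, 13092 and 9288 in N libraries 1, 2 and 3.

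Large changes outside these groups included Os12g0503000, with a ureide permease domain (chromosome 12, 19180665 to 19185915), which fell from 9458 ± 489.8 to 205 ± 55.6 normalised reads (log2 fold change -5.55 ± 0.171; limma, Benjamini-Hochberg adjusted p = 2.2e-06). Os07g0129300, with a cysteine-rich secretory protein domain, fell from 10242 ± 325 to 302 ± 170.3. Risers were Os03g0273200, with multicopper oxidase domains, from 142 ± 47.3 to 4118 ± 1245, and Os01g0704000, with an invertase and pectin methylesterase inhibitor domain next to NRT2.3, from 1.58 ± 1.43 to 163 ± 34.5. A gene model with a terpene synthase domain on chromosome 4, 16006919 to 16013230 rose from 15.9 ± 9.63 to 1031 ± 254.

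Phosphate genes mostly did not pass under N deficiency. Of the P starvation regulators 3 of 17 rose and 2 fell, with 7 passing when adjusted over the list alone; of the phosphate transporters 1 of 9 rose and 1 fell, with 3 passing when adjusted over the list alone; and of the SPX domain genes 2 of 13 rose and 1 fell, with 4 passing when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.36, 0.98 and 0.14). SPX-MFS2, with an SPX and a transporter domain, fell from 286 ± 100.3 to 19.8 ± 13.8 normalised reads. SPX1 had a log2 fold change of 0.23 ± 0.168 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.46), PHO2, which passed with DESeq2 and most edgeR fits, had 0.70 ± 0.196 (limma, Benjamini-Hochberg adjusted p = 0.051) and PT1 0.25 ± 0.162 (limma, Benjamini-Hochberg adjusted p = 0.40). PT4 fell by 0.95 on the log2 scale. PT9 had no read in control and 13 over the N libraries. It was 4.16-fold higher against a floor of 3 reads over the control group. With 1 library left out, the PT4 call (0.12) was lost without control library 1, 2 or 3 or N library 2 or 3. That of PT9 (0.081) was lost without control library 1 or 2 or N library 1 or 2. The highest adjusted p stands in parentheses, here and in the next sentence. Members that passed were SPX2, SPX-MFS1 and PHR4 (the last named after its values were seen) among the regulators that rose and SPX-MFS2 and PHR3 among those that fell, with calls lost for SPX2 (0.093) without control library 1 or 2 or N library 1 or 3; SPX-MFS1 (0.074) without control library 2 or N library 2 or 3; PHR3 (0.099) without control library 1, 2 or 3 or N library 3. Of the purple acid phosphatase genes 4 of 23 rose and 1 fell, with 5 passing when adjusted over the list alone, with Os12g0576600 at 2.92 ± 0.299 and Os12g0151000 the one that fell, and none of 13 glycerophosphodiester phosphodiesterase genes passed, with 0 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.10 and 0.88).

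The other lists did not pass as sets under N deficiency (camera, Benjamini-Hochberg adjusted p from 0.064 for histones to 0.91 for heat shock proteins). Peroxidase-domain genes rose in 22 and fell in 12 of 132 cases, 49 adjusted over the list alone, with Os06g0274800 at 2.15 ± 0.183 and Os04g0688300 at -2.29 ± 0.155. WRKY factors rose in 8 and fell in 4 of 84, 12 adjusted over the list alone, led by Os06g0504900 at 3.91 ± 0.405. Glutathione transferases rose in 12 and fell in 6 of 82 (20 adjusted over the list alone), lipoxygenase and jasmonate genes in 12 and 4 of 42 (20), and xyloglucan and cellulose enzymes in 9 and 3 of 52 (16). Glutaredoxins rose in 5 and fell in 3 of 30 (9 adjusted over the list alone), heat shock proteins in 4 and 4 of 83 (6), and histones in 5 and 0 of 42 (5). Ribosomal protein genes fell in 6 of 242 cases (2 adjusted over the list alone) and none rose. Of 21 response regulators Os09g0532400 fell by 1.77 on the log2 scale (1 adjusted over the list alone), and of 17 caspase-domain genes, matched by the pattern meant for Casparian strip proteins, Os03g0388900 rose by 2.48 (1 adjusted over the list alone). The ethylene pattern matched 18 genes, mostly CTR1-type kinases. The kinase gene Os01g0674100 rose and Os03g0214200, with repression and jasmonate signalling domains, fell (2 adjusted over the list alone). The rise, 0.32 ± 0.0854 on the log2 scale, was lost in 12 of 16 alternatives, most edgeR fits, DESeq2 and each library left out among them (adjusted p up to 0.16). Median, mean and set test differed in sign for peroxidase-domain genes, xyloglucan and cellulose enzymes, glutaredoxins, heat shock proteins, glutathione transferases and glycerophosphodiester phosphodiesterases.

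Leaving out control library 1, control library 2 or N library 3 lowered the count of passing genes from 4194 to 2749, 2633 and 2622. A fit with 1 library fewer also has less power, so lost calls alone do not show dependence on that library. Of 98 named genes that passed under N deficiency, 73 passed under each alternative and 25 missed the threshold in at least 1.

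The comparison of P deficiency with control asks the same of a shortage of phosphorus. SPX genes, whose proteins sense inositol pyrophosphates and restrain the phosphate starvation response, rose in 9 of 14 cases, phosphate transporters in 7 of 11 and purple acid phosphatases in 10 of 24. SPX5 (chromosome 3, 16645244 to 16646434) went from 68.4 ± 18.5 to 7070.1 ± 402 normalised reads, a log2 fold change of 6.70 ± 0.188 (limma, Benjamini-Hochberg adjusted p = 4.8e-06), and the transporter PT6 (chromosome 8, 28244202 to 28246028) from 8.84 ± 3.94 to 1966 ± 435, 7.70 ± 0.298 (limma, Benjamini-Hochberg adjusted p = 2.1e-05). The purple acid phosphatase gene Os11g0151700 rose from 304 ± 5.03 to 12201 ± 81.9, while the iron transporter gene YSL15 fell from 159 ± 57.2 to 3.91 ± 3.96. In all, 2047 of 32576 tested genes passed, 1166 higher and 881 lower under P deficiency, and 1040 of them changed by at least 1 on the log2 scale.

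Of 14 SPX domain genes 9 rose, none fell and 5 did not pass. The count was 11 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.1e-11; adjusted p = 0.04 with an estimated correlation). SPX1 rose from 142 ± 16.997 to 1855 ± 145 normalised reads, a log2 fold change of 3.70 ± 0.121 (limma, Benjamini-Hochberg adjusted p = 1.1e-05). SPX6 and SPX3 had 2 reads each over the control libraries, and their P deficiency to control ratios were 304.5 (95% counting interval 81.2 to 2438) and 45.5 (11.5 to 361). Of 18 P starvation regulators, many of them SPX genes, 9 rose and 2 fell. The count was 14 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.6e-05; adjusted p = 0.17 with an estimated correlation). The fallers were PHR3, a MYB-type factor, and NLA1, a ubiquitin ligase, at -0.60 ± 0.0923 and -0.97 ± 0.220, both named after their values were seen. PHO2, a ubiquitin-conjugating enzyme of phosphate homeostasis, had a log2 fold change of -0.43 ± 0.184 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.23).

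Phosphate transporters rose in 7 of 11 cases and none fell. The count was 8 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.5e-09; adjusted p = 0.08 with an estimated correlation). PT3 went from 5.71 ± 3.76 to 468 ± 190.2 normalised reads, PT4 from 91.1 ± 14.4 to 640.1 ± 76.6, PT2 from 116 ± 19.9 to 404 ± 81.3 and PT8 from 948 ± 175 to 3953 ± 413, with log2 fold changes of 6.17 ± 0.478, 2.80 ± 0.159, 1.78 ± 0.200 and 2.07 ± 0.148. PT9 and PT10, tandem genes that may share reads, had no read in control and means of 169 ± 56.2 and 104 ± 31.5 under P deficiency, at least 174-fold and at least 107-fold higher against a floor of 3 reads over the control group. PT1 had a log2 fold change of -0.02 ± 0.169 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.97), and neither did PT5 at 1.51 ± 0.641 (limma, Benjamini-Hochberg adjusted p = 0.23).

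Purple acid phosphatases rose in 10 of 24 cases and none fell. The count was 11 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.9e-10; adjusted p = 0.08 with an estimated correlation). Os12g0576600 went from 6.71 ± 1.19 to 1001 ± 98.96 normalised reads and Os08g0280100 from 10.6 ± 0.427 to 512 ± 102, and Os11g0151700 had a log2 fold change of 5.32 ± 0.0807 (limma, Benjamini-Hochberg adjusted p = 3.9e-07). Of 13 glycerophosphodiester phosphodiesterase genes, whose enzymes break down deacylated phospholipids, 5 rose and 5 passed when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.7e-05; adjusted p = 0.08 with an estimated correlation). Os03g0603600 went from 229.7 ± 15.7 to 3541 ± 769 and Os02g0514500 from 27.02 ± 4.09 to 298 ± 17.5. The call of Os04g0394100 was lost without control library 1 or 2 or P library 2 (adjusted p up to 0.063), and Os01g0763600, named after its values were seen, and Os08g0535700 were the remaining members that passed. Os08g0299400, with a monogalactosyldiacylglycerol (galactolipid) synthase domain (chromosome 8, 12266091 to 12269520), rose from 12.4 ± 5.32 to 2842 ± 295, a log2 fold change of 7.79 ± 0.258 (limma, Benjamini-Hochberg adjusted p = 1.1e-05). Os11g0658900, a class 3 lipase gene, rose from 4.65 ± 2.13 to 794 ± 110.5.

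Nitrogen genes leaned down. Nitrate and ammonium transporters fell in 5 and rose in 1 of 16 cases. The count was 7 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.033; adjusted p = 0.50 with an estimated correlation). NAR2.1 fell from 2161 ± 274 to 899.9 ± 270.0 normalised reads and NRT1.1B from 4808 ± 929.8 to 1550.5 ± 597, NRT2.2 fell by 1.32 on the log2 scale, named after its values were seen, while NRT2.4 rose from 20.8 ± 7.19 to 75.7 ± 30.96. AMT1;3 had 0 reads under P deficiency and 16 over the control libraries, 5.03-fold lower against a floor of 3 reads over the P group. AMT1;2 fell by 1.45 on the log2 scale. Of the NAR2-type pair, Os04g0480200 did not pass, at -0.49 ± 0.277 (limma, Benjamini-Hochberg adjusted p = 0.37). Nitrogen assimilation genes fell in 3 of 16 cases. The count was 7 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.002; adjusted p = 0.17 with an estimated correlation). The fallers were NIA1 from 4358 ± 1814 to 1465 ± 126, NIA2 from 7981 ± 4004 to 2526 ± 269 and NADH-GOGAT2 from 24.9 ± 2.16 to 5.25 ± 2.65. Calls lost in some fits with 1 library left out were NAR2.1 (0.081) without control library 1, 2 or 3 or P library 1; NRT1.1B (0.078) without control library 1 or 3 or P library 1; NRT2.4 (0.12) without control library 1 or 2 or P library 1 or 2; AMT1;3 (0.15) without control library 1 or 3 or P library 1, 2 or 3; AMT1;2 (0.13) without control library 1 or 3 or P library 1 or 2; NIA1 (0.059) without P library 1 or 2; NIA2 (0.10) without control library 1 or P library 1 or 2; NADH-GOGAT2 (0.10) without control library 1, 2 or 3 or P library 1 or 2, with the highest adjusted p over the alternatives in parentheses. The AMT1;2 and AMT1;3 calls were also lost with the replicate block, and that of AMT1;3 with most edgeR fits. NRT2.1 did not pass at -1.45 ± 0.357 (limma, Benjamini-Hochberg adjusted p = 0.06), nor GS1;2 at -1.42 ± 0.358 (limma, Benjamini-Hochberg adjusted p = 0.064); both passed in 7 of 16 alternatives, most edgeR fits and DESeq2 among them.

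Among 6 nitrate-response regulators 1 rose and 1 fell. The count was 3 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.66). NIGT1 rose from 131 ± 18.2 to 1340.0 ± 86.9 normalised reads, a log2 fold change of 3.35 ± 0.126 (limma, Benjamini-Hochberg adjusted p = 2.0e-05), and LBD38 fell by 0.94, a call lost without control library 1 or P library 1 or 2 (adjusted p up to 0.062). Iron uptake genes fell in 9 and rose in 1 of 14 cases. The count was 12 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.9e-05; adjusted p = 0.26 with an estimated correlation). IRO2 went from 369 ± 31.9 to 47.1 ± 18.2 and YSL15 had a log2 fold change of -5.26 ± 0.588. NAS1 and NAS2 had -3.47 ± 0.697 and -3.22 ± 0.606, calls lost with the replicate block or without control library 1, 2 or 3 or P library 2 (adjusted p up to 0.12 and 0.098). NAS3, named after its values were seen, was again the riser, at 0.85 ± 0.110. Of 8 strigolactone genes 3 rose and 1 fell. The count was 5 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.079). The list passed with the rotation test (fry, Benjamini-Hochberg adjusted p = 0.0049). NSP1 rose from 38.5 ± 4.81 to 918 ± 164 and D10 from 20.3 ± 1.54 to 138 ± 27.1. The other members that passed, NSP2 and D14, lost their calls without control library 1, 2 or 3 or P library 1 or 2 (adjusted p up to 0.11 and 0.11).

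Photosynthesis genes leaned down as a set, although 1 of 44 fell and 0 passed when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.2e-05; adjusted p = 0.60 with an estimated correlation). The faller was the chlorophyll a-b binding gene Os04g0690800, at -1.39 ± 0.290, a call lost without control library 2 or 3 or P library 1 or 2 (adjusted p up to 0.12). Summed reads of the list were 31232, 22656 and 30600.2 in P libraries 1, 2 and 3. Xyloglucan and cellulose enzymes leaned up (2 rose and 1 fell of 51, 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0088; adjusted p = 0.58 with an estimated correlation). An example was the cellulose synthase gene Os10g0467800 at 1.00 ± 0.221, a call lost without control library 1 or 2 or P library 1 or 2 (adjusted p up to 0.16). The CTR1-type kinase list leaned down (1 fell of 18, 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0047; adjusted p = 0.41 with an estimated correlation). Its faller, Os03g0214200, with repression and jasmonate signalling domains, had -0.60 ± 0.0950, a call lost without control library 1 or 2 or P library 2 (adjusted p up to 0.072).

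No other list passed as a set under P deficiency (camera, Benjamini-Hochberg adjusted p from 0.051 for ribosomal proteins to 0.89 for diterpenoid phytoalexin genes). Glutathione transferases rose in 11 and fell in 2 of 82 cases (14 adjusted over the list alone), with Os03g0283200 from 104 ± 13.3 to 632 ± 133 normalised reads. Peroxidase-domain genes rose in 2 and fell in 5 of 134 (7 adjusted over the list alone), WRKY factors in 1 and 2 of 84 (3), amino acid transporters in 2 (Os01g0908600 and Os04g0543600) and 3 (Os01g0825800, Os02g0191300 and Os06g0633800, the last named after its values were seen) of 83 (5), and heat shock proteins in 2 and 3 of 83 (5). Lipoxygenase and jasmonate genes rose in 2 and fell in 1 of 42 (10 adjusted over the list alone), ribosomal protein genes in 1 (Os07g0207301) and 2 (Os01g0633000 and Os03g0856500) of 242 (0), and histones in 1 and 2 of 42 (5). Among these, calls were lost for Os01g0908600 (0.067) without control library 1 or 2 or P library 2; Os04g0543600 (0.10), Os01g0633000 (0.15) and Os03g0856500 (0.12) without control library 1, 2 or 3 or P library 1 or 2; Os07g0207301 (0.062) without control library 1 or P library 1 or 2, with the highest adjusted p in parentheses. Glutaredoxins rose in 2 of 30 (2 adjusted over the list alone), Os05g0198200 among them at 1.16 ± 0.165. The response regulator Os09g0532400 fell by 1.06 on the log2 scale, alone among 21 (1 adjusted over the list alone), and none of 17 caspase-domain or 8 diterpenoid phytoalexin genes passed (0 and 0 adjusted over the list alone). Median, mean and set test differed in sign for diterpenoid phytoalexin genes, nitrate-response regulators, WRKY factors and peroxidase-domain genes.

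Without control library 1, 2 or 3 the count of passing genes under P deficiency was 696, 753 and 1202, and without P library 1 or 2 it was 827 and 934. Without P library 3 it rose to 3384, and of 84 named genes that passed, 39 passed under each alternative and 45 missed the threshold in at least 1.

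**Figure D2:**
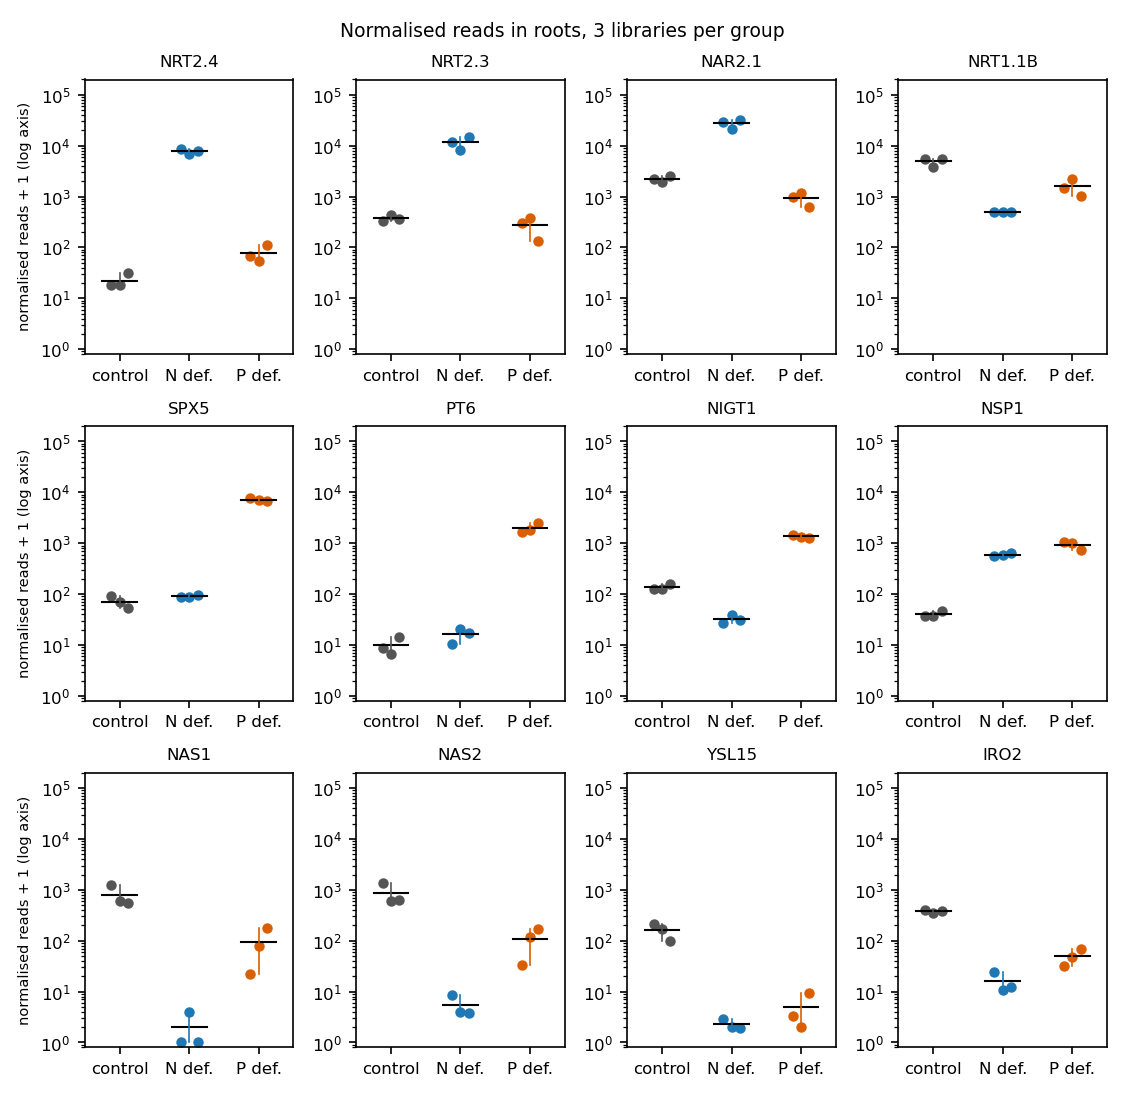
Normalised reads + 1 on a log axis for 12 genes, with 1 point per library, a horizontal bar at the group mean and a vertical line from the lowest to the highest library. NRT2.4, NRT2.3 and NAR2.1 stand highest under N deficiency, SPX5, PT6 and NIGT1 highest under P deficiency, and NAS1, NAS2, YSL15 and IRO2 highest in control.

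Set directly against each other, N and P deficiency differed in nitrate transporter and phosphate starvation genes. NRT2.1 stood at 1207 ± 187 normalised reads under N deficiency and 3.89 ± 0.956 under P deficiency, a log2 ratio of N over P of 7.96 ± 0.240 (limma, Benjamini-Hochberg adjusted p = 6.8e-08), and SPX5 at 89.1 ± 6.05 normalised reads under N deficiency and 7219 ± 416 under P deficiency, -6.32 ± 0.171 (limma, Benjamini-Hochberg adjusted p = 6.0e-08). NIGT1, which lay on opposite sides of control in the 2 deficiencies, had -5.43 ± 0.163 (limma, Benjamini-Hochberg adjusted p = 6.8e-08). This test covered all 9 libraries on a common scale, and 1243 of 33120 genes passed, 455 higher under N deficiency and 788 higher under P deficiency.

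Higher under N deficiency were 8 of 16 nitrate and ammonium transporters, against 1 lower. The count was 12 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.8e-11; adjusted p = 0.072 with an estimated correlation). NRT2.4 stood at 7816 ± 879.6 normalised reads under N deficiency and 77.2 ± 31.2 under P deficiency and NAR2.1 at 27550.3 ± 5454 normalised reads under N deficiency and 919.9 ± 280.5 under P deficiency. Os04g0480200, the other NAR2-type gene, had a log2 ratio of 4.61 ± 0.237, and NRT1.1B, the transporter that was lower, -1.60 ± 0.248. Nitrogen assimilation genes were higher in 5 of 16 cases. The count was 7 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.4e-04; adjusted p = 0.08 with an estimated correlation). Examples were NADH-GOGAT2 at 4.09 ± 0.372 and GS1;1 at 1.29 ± 0.235. Amino acid transporters were higher in 7 and lower in 1 of 84. The count was 14 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.5e-04; adjusted p = 0.08 with an estimated correlation). Diterpenoid phytoalexin genes were higher in 2 of 8, CPS4 and CYP99A3. The count was 4 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.2e-04; adjusted p = 0.41 with an estimated correlation). WRKY factors were higher in 4 and lower in 3 of 84. The count was 12 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0088; adjusted p = 0.76 with an estimated correlation). An example was Os06g0504900 at 4.30 ± 0.554. The CTR1-type kinase list leaned higher with no gene past the threshold of 18 (0 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.047; adjusted p = 0.58 with an estimated correlation).

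Higher under P deficiency were 9 of 14 SPX domain genes, 7 of 11 phosphate transporters and 4 of 13 glycerophosphodiester phosphodiesterases, with none higher under N deficiency and 11, 7 and 5 passing when adjusted over the list alone. These 3 lists passed both ways (camera, Benjamini-Hochberg adjusted p = 6.0e-11, 1.6e-11 and 7.5e-06; adjusted p = 0.036, 0.04 and 0.04 with an estimated correlation). PT6 stood at 15.1 ± 5.35 normalised reads under N deficiency and 2006 ± 435 under P deficiency, SPX1 at 170.3 ± 29.9 normalised reads under N deficiency and 1894 ± 139 under P deficiency and Os03g0603600 at 276 ± 22.9 normalised reads under N deficiency and 3618 ± 797 under P deficiency. Purple acid phosphatases were higher under P deficiency in 9 and lower in 1 of 24 cases. The count was 12 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.4e-08; adjusted p = 0.08 with an estimated correlation). P starvation regulators were higher under P deficiency in 9 and lower in 2 of 18. The count was 13 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.2e-05; adjusted p = 0.08 with an estimated correlation). PHO2 and NLA1, the latter named after its values were seen, were the regulators higher under N deficiency, PHO2 at 1.13 ± 0.189, and Os12g0637000 was the phosphatase. The ureide permease gene Os12g0503000 stood at 199.8 ± 54.04 normalised reads under N deficiency and 10502 ± 1048 under P deficiency, and Os07g0129300 at 294 ± 166 normalised reads under N deficiency and 29654 ± 4101 under P deficiency.

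Iron uptake genes were lower under N than under P deficiency in 5 of 14 cases and higher in 1. The count was 10 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.6e-04; adjusted p = 0.26 with an estimated correlation). Examples were IRO2 at -1.65 ± 0.344 and NAS2 at -4.11 ± 0.590; the higher gene was the iron transporter IRT1, at 1.48, named after its values were seen. Photosynthesis genes were lower under N deficiency in 11 of 44 cases. The count was 28 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.4e-15; adjusted p = 0.26 with an estimated correlation), and Os07g0178700 had -5.20 ± 0.657. Strigolactone genes leaned lower, with 1 lower and 1 higher of 8 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.043; adjusted p = 0.41 with an estimated correlation). Of the pair, D10 was the lower one, at -0.91 ± 0.198, and D53, named after its values were seen, the higher one, at 0.69. Ribosomal protein genes leaned lower with 1 of 242 past the threshold, Os10g0500500, named after its values were seen, and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.2e-05; adjusted p = 0.78 with an estimated correlation). 

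The remaining lists did not pass as sets between the deficiencies (camera, Benjamini-Hochberg adjusted p from 0.20 for glutathione transferases to 0.99 for peroxidase-domain genes). Higher and lower under N deficiency were 2 and 2 of 6 nitrate-response regulators (4 adjusted over the list alone), 5 and 3 of 134 peroxidase-domain genes (13), 1 and 7 of 83 glutathione transferases (11), and 1 and 2 of 52 xyloglucan and cellulose enzymes (3). The counts were 0 and 2 of 42 for lipoxygenase and jasmonate genes (2 adjusted over the list alone), 1 and 1 of 83 for heat shock proteins (1), 0 and 2 of 21 for response regulators (Os07g0449700 and Os09g0532400, the former named after its values were seen; 2), 1 and 0 of 42 for histones (1), 1 and 0 of 17 for caspase-domain genes (Os03g0388900; 1) and 0 and 0 of 30 for glutaredoxins (0). Median, mean and set test differed in sign for peroxidase-domain genes, histones and response regulators. Without N library 1, N library 3 or P library 2 the count of genes that differed between the deficiencies fell to 729, 692 and 742.

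The design text asks which genes tie nitrogen and phosphorus supply together, so the genes that passed in both comparisons with control were counted. NSP1 rose by 3.89 ± 0.150 under N deficiency and 4.53 ± 0.175 under P deficiency on the log2 scale (limma, Benjamini-Hochberg adjusted p = 8.7e-06 and 2.1e-05). IRO2 had -4.67 ± 0.297 and -3.01 ± 0.272. NIGT1 fell under N deficiency and rose under P deficiency, at -2.09 ± 0.215 and 3.35 ± 0.126. In all 1280 genes passed in both, 663 higher in both, 573 lower in both and 44 in opposite directions.

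Other genes that rose in both were Os10g0116800, with a calcineurin-like phosphoesterase domain, by 3.47 ± 0.362 and 6.42 ± 0.356 on the log2 scale, Os12g0555100, with a polyketide cyclase domain, by 4.15 ± 0.319 and 2.99 ± 0.326, and Os06g0185500, with an acyl transferase family domain, by 3.56 ± 0.370 and 2.84 ± 0.352. Lower in both were YSL15, NAS1, NAS2 and Os02g0137700, the last with a complex I intermediate-associated domain, at -5.19 ± 0.314 and -2.96 ± 0.441. Its call under P deficiency was lost without control library 2 (adjusted p = 0.051). Those of NAS1 and NAS2 were lost with the replicate block or without control library 1, 2 or 3 or P library 2 (adjusted p up to 0.12 and 0.098). Among the 44 opposite genes, 34 were lower under N and higher under P deficiency and 10 the reverse. Os02g0668500, with a CRAL/TRIO domain, had -2.38 ± 0.274 under N and 2.93 ± 0.217 under P deficiency, Os02g0822900, with U-box and kinase domains, -1.68 ± 0.192 and 2.46 ± 0.190, and Os08g0140500, a pyridoxal-dependent decarboxylase gene, -2.14 ± 0.195 and 1.63 ± 0.146. Os10g0580400, with a sodium:solute symporter domain, rose from 2772 ± 855 to 14817 ± 4159 normalised reads under N deficiency and fell from 2642 ± 796 to 799.8 ± 223 under P deficiency. All 44 also passed the direct test of N against P deficiency, as did 137 of the 1236 genes with a shared direction, among the genes tested in both comparisons, 505 of 2905 called under N deficiency alone and 313 of 751 called under P deficiency alone. The 44 were picked for passing on opposite sides of control in these same libraries. That choice favours a pass in the direct test, so it is not separate evidence.

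**Figure D3:**
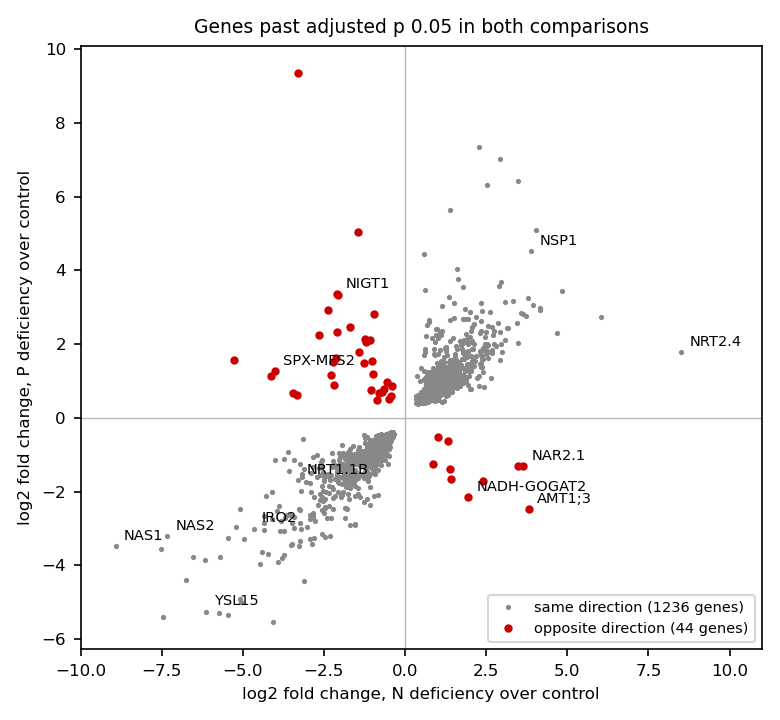
Log2 fold change under P deficiency against that under N deficiency, both over control, with 1 point per gene that passed in both comparisons. Grey points mark 1236 genes with a shared direction and red points 44 with opposite directions, NIGT1 and NAR2.1 among them; both axes share the control libraries.

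Independent lists of the same lengths among the 32012 genes tested in both would share 80.6 higher, 53.4 lower and 131 opposite genes. In 20 simulations of unchanged groups against the shared controls no gene passed in both. At most 2 genes passed in either simulated comparison, so this cannot show how far shared controls add to the overlap among changed genes. Log2 fold changes correlated at 0.609 across genes, which are not independent replicates, against 0.525 in the simulations, and their covariance was 0.285 against 0.0828, a difference of 0.203. The 3 control libraries are too few to divide, so part of the excess may come from the shared controls. Without control library 1, 2 or 3 the shared count was 372, 414 and 765, and without P library 1 or 2 it was 534 and 612.

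The authors' deposited tables list 2301 genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1 under N deficiency, 1093 higher and 1208 lower, and 2105 of them also passed limma here. Under P deficiency the authors' deposited table lists 1359 such genes, 776 higher and 583 lower, and 993 of them also passed limma. Both tables hold 801 genes in common, 380 higher, 392 lower and 29 in opposite directions. All 4194 and 2047 genes that passed limma had the same sign in the authors' deposited tables. In edgeR's quasi-likelihood test on the recovered reads, 3997 genes passed under N deficiency and 2776 under P deficiency, as an alternative added after the data were seen. Between the deficiencies 1330 passed, where edgeR was fitted first and limma was chosen after that count was seen. Of these, 3579, 1910 and 1181 also passed limma.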

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

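The edgeR fit with TMM and the limma fit of N and P deficiency over 9 libraries were chosen only after the data were seen. So were the authors' tables without a fold limit. For N against P deficiency edgeR was the first fit. The other alternatives were planned. No gene called in the reported fits was called in the opposite direction in any fit over all genes. The signs of genes that lost their call were not counted. The edgeR, pseudocount, filter and library-set alternatives left the gene counts within 1.5 times. DESeq2 called 3801 genes under P deficiency, 2276 between the deficiencies and 2325 in both; the cause was not tested. With an absolute log2 fold change of at least 1, 2213, 1040, 746 and 603 genes passed for N deficiency, P deficiency, N against P deficiency and both, by construction fewer. With 1 library left out the counts ranged from 2622 to 3710, 696 to 3384, 692 to 1486 and 372 to 1805, the highest of the last 3 without P library 3. Part of the losses may come from the lower power of these fits. With an estimated correlation 4 gene list tests passed in place of 31. With fry 28 passed, with 10 calls lost and 7 gained. Lost under N deficiency was the diterpenoid list. Lost under P deficiency were nitrate and ammonium transporters, the CTR1-type kinase list, xyloglucan and cellulose enzymes and photosynthesis genes. Between the deficiencies the strigolactone, diterpenoid, WRKY, CTR1-type kinase and ribosomal protein calls were lost. Strigolactone genes and glutathione transferases were among those gained, under both deficiencies. Without a fold limit the authors' deposited tables list 4828 and 3282 genes. Over all alternatives, named genes kept their side of the threshold in 2832 values, gained it in 29 and lost it in 309, and lists in 176, 11 and 38. Whether replicate numbers pair the samples was not settled. Deviations of number 1 correlated at -0.10, 0.04 and -0.12 between the groups, against 0.22 to 0.40 for numbers 2 and 3. Libraries numbered 2 and 3 correlated best with their own number in each other group, and those numbered 1 did not. With the replicate block 4661, 2106, 1513 and 1376 genes and 34 lists passed. Among the named genes 8 calls were lost with it, those of AMT1;2, AMT1;3, NAS1 and NAS2 under P deficiency among them, and 1 was gained.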

Other observations

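The domain tests, the tests of levels without 1 control library, the test of shared controls for the iron genes and the 3 tests on P library 3 were tests chosen only after the result was seen. The hypergeometric tests, those on P library 3 included, treat genes of 1 family as independent. Their p-values measure the sampling of genes and not the spread between replicate libraries. Water channel genes, which the aquaporin list missed, fell under N deficiency in 14 of 42 cases (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p = 9.1e-05). Os01g0975900 went from 48064 ± 17881 to 8134 ± 2165 normalised reads, a log2 fold change of -2.53 ± 0.288 (limma, Benjamini-Hochberg adjusted p = 0.001), and Os04g0521100 had -1.94 ± 0.210. Sugar efflux transporter genes of the SWEET type rose in 7 of 13 cases (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p = 0.011), with Os12g0476200 from 66.9 ± 18.9 to 749 ± 197. Genes of the NF-YA family, subunits of a CCAAT-binding transcription factor, rose in 6 of 10 cases (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p = 0.013), with Os02g0776400 at 1.97 ± 0.146 and Os03g0647600 at 1.61 ± 0.0984. The genes named here were chosen after their values were seen.

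Multicopper oxidase genes rose under N deficiency in 14 of 42 cases (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p = 0.0035), among them Os01g0127200 at 3.17 ± 0.403 and LPR3 at 2.35 ± 0.217 on the log2 scale, both also higher under P deficiency at 2.45 ± 0.388 and 2.63 ± 0.165. Genes with a tify domain, found in repressors of jasmonate signalling, rose in 8 of 19 cases (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p = 0.017) and COBRA-like genes, a family with cell wall roles, in 6 of 10 (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p = 0.013). Under P deficiency bZIP factors fell in 9 of 72 cases (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p = 0.019), with Os12g0634500 at -2.36 ± 0.347 (limma, Benjamini-Hochberg adjusted p = 0.0099).

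Photosynthesis genes were lower under N deficiency in 31 of 44 measured cases, and these roots expressed 44 of the 45 listed genes past the filter. Green shoot tissue in the control libraries may account for part of this. The 8 leaf enzyme genes outside the list had a median log2 fold change of -1.75. Of these, 6 of 8 passed as lower, although the carbonic anhydrase gene CA rose by 0.68. Levels outside the control libraries argue against shoot tissue in those libraries alone as the whole cause. Summed reads of the list were 31232, 22656 and 30600 under P deficiency and 10482, 13092 and 9288 under N deficiency. In the direct test 11 of 44 genes were lower under N than under P deficiency and 0 higher. Shoot tissue in the P libraries too was not tested. Of the 8 leaf enzyme genes, RCA stood at 4221 ± 2208 normalised reads in control and 1024 ± 178 under N deficiency, and CA at 5379.7 ± 712 in control. A single deviating control library is argued against as the whole cause: the median log2 level of the 44 genes stayed 2.06 ± 0.240, 1.70 ± 0.503 and 1.39 ± 0.273 (SE) above N deficiency without control library 1, 2 or 3, though the planned bound on kept calls was not met, at 31, 21 and 26 of 31 genes. A response of root plastid genes to N supply could lower the 8 leaf enzyme genes alike, so their fall cannot separate it from shoot tissue. Such a response stays open and was not tested.

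Iron uptake genes were lower in both deficiencies for 8 members. The 8 genes stood higher in every control library than in any N or P library. Their median log2 level stayed at least 2.75 ± 0.730 (SE) above P deficiency without any 1 control library. These levels cannot decide on a single deviating control library, since the 8 genes were picked by passing against these same controls. The planned bound on kept calls was not met, at 5 of 8, nor was a first bound on levels, a gap of 1.77 between the lowest control and the highest P library against a range of 1.96 within P libraries. High levels in all the shared control libraries cannot be told apart from a response: 4 of 8, IRO2, NAS1, NAS2 and NAAT1, were lower under N than under P deficiency in the direct test, which leaves the fall common to both open. A response of iron uptake to N and P supply stays open and was not tested.

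P library 3 stood apart from the other P libraries, with 60 genes depleted in it by at least 4 on the log2 scale, 8 of them with a peroxidase domain, and 42 enriched by at least 3, 8 of them with an AP2 domain (hypergeometric test, Benjamini-Hochberg adjusted p = 1.7e-08 and 3.9e-10). A mislabelled control or N library is argued against, since 9 of 9 SPX domain genes called without P library 3 stood above each control and N library there, and so is lower depth, at 21.1 M reads. The depleted genes also differed between N libraries, with medians of 29.2, 103 and 16.6 normalised reads in N libraries 1, 2 and 3, against 108, 126 and 91.9 in control libraries. Their median log2 range over the N libraries was 2.45, against at most 0.598 in 1000 random lists of matched level. The lists were matched on level in control and not on variability, so the excess cannot single out a shared axis. An axis of tissue makeup or handling that varies within the N and P groups but little within control stays possible. Such an axis may add to the spread behind the 2047 calls under P deficiency and the 3384 without this library.

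The 10 splits of 6 libraries are too few for a share under 0.05. The real split gave the most calls, 1 of 10, in each comparison: 4194 genes under N deficiency and 2047 under P deficiency, with 0 in the highest other split by limma (3182 and 2314 genes at an unadjusted p under 0.05). Between the deficiencies it gave 1243, with 441 in the highest other split, which set N libraries 1 and 3 with P library 3. Among 100 splits of all 9 libraries on a common scale, only the real split itself, 1 of 100, reached 1287 genes in both deficiencies. The highest other, which kept the controls together and mixed N with P libraries, gave 903, and another that kept the controls together gave 463. Splits whose control group mixed libraries of different real groups gave 0. The share speaks against an arbitrary grouping of the libraries. It cannot tell how much of the count comes from the shared controls standing apart. For gene list tests only the real split, 1 of 100, reached 32. The other splits gave 6 to 30, the highest from a split that kept the P libraries together. The real count stands little above other groupings, so chance is not excluded for the list calls.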
